A study of Mus musculus with 16 samples.

How the data were processed

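RNA sequencing reads from skeletal muscle of male C57BL/6N mice were used, from 16 libraries of 4 groups: wild type and NADS knockout, each at 2 and at 24 months of age, with 4 libraries per group. The labels do not spell out NADS, and the gene was taken to be Nadsyn1, whose reads were checked in every library. They do not state which muscle was taken, whether the libraries were stranded, whether each library came from a separate animal, or whether the replicate numbers pair libraries across groups. Total RNA was extracted with a phenol reagent and column purification, and sequenced on an Illumina instrument, per the labels.

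The deposited table holds, for each library and each of 41961 genes, counts of reads: all reads in exons, reads mapped uniquely in exons, and reads in introns. The counts are raw, and the sums over genes come to 18560480 to 28152454 exon reads per library. The table also holds the authors' fold changes, written with a sign, and the authors' p-values after correction for the false discovery rate, from an EDGE test with tagwise dispersions per the file headers. Genome builds GRCm38 and mm10 are named in the submitters' processing notes, and the aligner and the annotation release are not given in the sources used here. Gene IDs were looked up in a mouse gene table, and 41924 matched. Where genes share a symbol the table numbers them. The gene called Nnt here is the first of its 2 entries, and the second held no reads.

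All counts here are total exon reads per gene. Genes were kept by filterByExpr with its minimum count of 10, which left 14579 genes. Libraries were scaled by TMM factors. The comparisons were old against young in the wild type, old against young in the knockout, knockout against wild type at 2 months and at 24 months, and the interaction of age and genotype, which is the age response of the knockout minus that of the wild type. Each was tested with the quasi-likelihood test of edgeR 4.0.16 in one fit of all 16 libraries with 12 residual degrees of freedom, and p-values were adjusted over all tested genes by Benjamini-Hochberg, with a gene called at an adjusted p under 0.05. The common biological coefficient of variation was 0.33. Standard errors were taken from the fold change and its F statistic. Levels are CPM with TMM factors, and log2 CPM used a prior count of 2. A count of 0 in a library allows a level of up to 0.0831 to 0.163 CPM, taking 3 counts as its limit, which covers counting error only. Where a group mean lies below this level, as for Krt18 and Krt8 in young muscle, the size of the fold change rests on few reads.

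Before the data were examined, 46 lists of genes were fixed: metabolic pathways, muscle fibre proteins, stress responses and markers of cell types that muscle can hold. Each was tested with camera from limma 3.58.1 with a preset correlation of 0.01, with the p-value adjusted over the 46 lists. Each was tested again with an estimated correlation and with fry. No list that camera called was called with an estimated correlation in any of the comparisons. Fry, which asks whether the genes of a list move 1 way on balance, called 8 of the 10 lists called with age in the wild type, 8 of 15 with age in the knockout, 1 of 16 at 2 months, 0 of 12 at 24 months and 0 of 9 in the interaction. Counts adjusted over the list alone use the genes of that list only. The adjusted p of camera on its own therefore rests on the preset correlation.

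Genes were named by a rule fixed before the data were examined. It takes Nadsyn1 and Nnt; up to 6 genes higher and 6 lower of largest change among called genes of at least 1 CPM whose libraries do not overlap between groups, without predicted genes, clones and immunoglobulin segments; from each list that passed camera or held called genes, up to 4 called genes of smallest adjusted p, or up to 2 of smallest p where none was called; and 5 in each direction for the interaction. Some of the genes that it gives are left out for length, and some are not reported here. Other genes are named in the text on libraries, and were chosen after their values were seen.

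The method was tested on simulated data, with the depth, mean levels and dispersions of these libraries and known changes added to 100 genes per fold. Each gene was drawn independently of the others. Of genes changed 2-fold, 31%, 33%, 30%, 33% and 9% were recovered in the order of comparisons above, and of genes changed 4-fold 75%, 86%, 78%, 79% and 62%. False calls numbered 6, 3, 1, 9 and 6. The simulation held no differences between libraries that many genes share, so these numbers do not cover such differences in the real libraries.

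Alternatives were DESeq2 1.42.0 as size factors and as a test, upper-quartile factors, limma-voom with quality weights, no filter, a filter of 1 CPM in each library of a group, a fit of the groups compared alone, a minimum log2 fold change of 1, a replicate block, and leaving out each library in turn. Chosen after the data were seen were unique exon reads, leaving out libraries with high lymphocyte markers, leaving out the fourth young and the fourth old wild type library, the lymphocyte marker mean as a covariate, and a correction of each library for gene length and GC content. Groupings of the same libraries other than the real one were counted for each comparison. Intron reads were tested in the same way as exon reads and are described apart from the main comparisons. The authors' fold changes and p-values were used only to set their calls beside those made here. R 4.3.3 and Python 3.11.15 were used.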

Results

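RNA was sequenced from skeletal muscle of male C57BL/6N mice that were wild type or carried the NADS knockout, at 2 months of age (young) or 24 months of age (old). Each of the 4 groups held 4 libraries, 16 in all. Reads in exons came to 24003086 to 26462502 per library in young wild type, 22536648 to 25784748 in old wild type, 18560480 to 28152454 in young knockout and 20281552 to 21694938 in old knockout. A read was found for 16552 to 18719 genes per library, and 14579 genes were tested. The labels do not state that each library came from a separate animal, so the p-values measure the spread between samples. Log2 fold changes are given with their standard error (SE) and levels as counts per 1e6 reads (CPM) with their standard deviation (SD), over 4 libraries per group throughout.

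The first question was whether the knockout label shows in the reads of the gene itself. Nadsyn1, which encodes the NAD synthetase that makes NAD from its acid form (ENSMUSG00000031090, chromosome 7 from 143795584 to 143822849), had 33 to 85 exon reads in each of the 8 wild type libraries and 2 to 12 in each of the 8 knockout libraries. Its level was 2.30 CPM (SD 1.15, n = 4) in young wild type, 2.17 CPM (SD 0.738) in old wild type, 0.209 CPM (SD 0.0957) in young knockout and 0.385 CPM (SD 0.161) in old knockout. Nadsyn1 was lower in the knockout at 2 months, with a log2 fold change of -3.44 (SE 0.48, adjusted p = 0.00248). At 24 months the log2 fold change was -2.48 (SE 0.46, adjusted p = 0.105). The interaction of age and genotype gave 0.97 (SE 0.64, adjusted p = 0.502) for this gene. In exon reads every library thus lay on the side of Nadsyn1 that its genotype label gives. In intron reads old knockout replicate 1 had 11 and old wild type replicate 4 had 9.

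**Figure D1:**
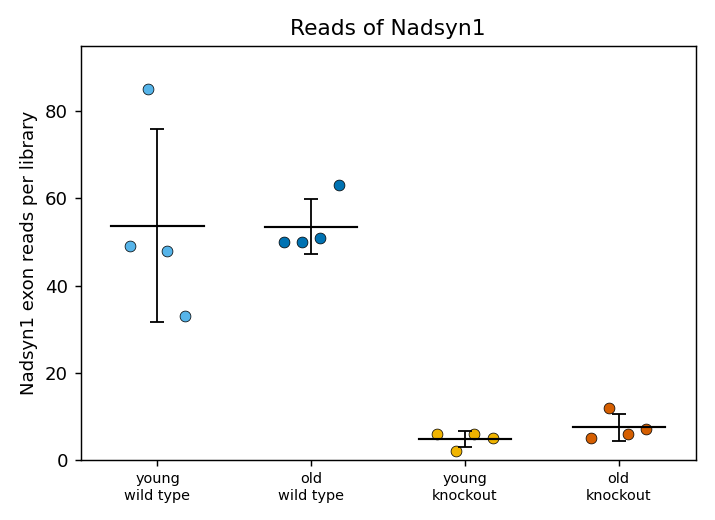
Exon reads of Nadsyn1 in each library (points), with the mean and SD of the 4 libraries of each group (line and bar). The 8 wild type libraries lie between 33 and 85 reads and the 8 knockout libraries between 2 and 12.

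Nnt, the mitochondrial transhydrogenase that couples NADH to NADPH, was read in every group. Its level was 116 CPM (SD 27.5) in young wild type, 190 CPM (SD 80.9) in old wild type, 111 CPM (SD 20.9) in young knockout and 345 CPM (SD 72.1) in old knockout. Nnt rose with age in the knockout (log2 fold change 1.64, SE 0.28, adjusted p = 0.00268). In the wild type its log2 fold change with age was 0.71 (SE 0.27, adjusted p = 0.0887), and the difference between these responses was 0.93 (SE 0.39, adjusted p = 0.268). Between genotypes its log2 fold change was -0.06 (SE 0.27, adjusted p = 0.946) at 2 months and 0.86 (SE 0.27, adjusted p = 0.212) at 24 months.

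The libraries differed in ways that the groups do not give. The pooled mean of B and T lymphocyte markers was high in 5 libraries and low in the other 11. This mean, as log2 CPM centred over all libraries, was 3.73 and 3.54 in young wild type replicates 1 and 4, 4.30 and 1.37 in old wild type replicates 1 and 3, and 2.71 in young knockout replicate 3. The highest of the other 11 libraries was at -0.846. For T and natural killer cell markers alone, old wild type replicate 3 (0.179) was below old knockout replicate 4 (0.217), so that it stands apart by its B and plasma cell markers (2.56, against -1.95 to -1.16 in the 11 libraries). Another difference, chosen after its values were seen, was that of Rps29, a ribosomal protein gene, which was at 27.6 to 32.0 CPM in young wild type replicates 1 to 3 but at 104 CPM in replicate 4, and at 182 to 263 CPM in old wild type replicates 1 to 3 but at 28.4 CPM in replicate 4. It was at 84.1 to 148 CPM in young knockout and 31.2 to 87.1 CPM in old knockout. The first principal component held 27.8% of the variance and the second 21.4%. Within groups the median correlation of log2 CPM between libraries was 0.945 in young wild type, 0.929 in old wild type, 0.968 in young knockout and 0.968 in old knockout.

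**Figure D2:**
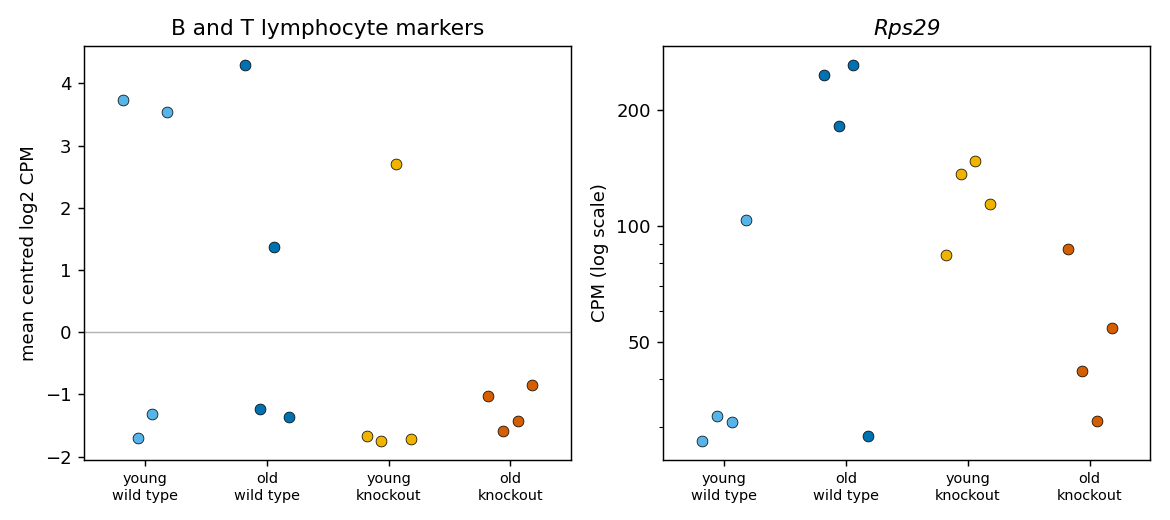
Left, the mean of the B and T lymphocyte markers in each library, as log2 CPM centred over all libraries. Right, the level of Rps29 in CPM on a log scale. Points are single libraries, in replicate order from left to right within each group. The lymphocyte marker mean is at or above 1.37 in 5 libraries and at or below -0.846 in the others.

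The second question was what changes between 2 and 24 months in wild type muscle. Old wild type muscle had more RNA of Krt18 and Krt8, of sarcolipin and of 13 of 25 genes of denervation and the neuromuscular junction. It had less RNA of 22 of 33 collagen and matrix genes, 9 of 12 tendon markers and 11 of 15 fibroblast markers. Camera called these 4 lists, and adjusted p = 0.342 to 0.591 with an estimated correlation. Krt18, a keratin of simple epithelia, was at 33.4 CPM (SD 21.9, n = 4) in old and 0.105 CPM (SD 0.134, n = 4) in young wild type (log2 fold change 8.25, SE 0.82, adjusted p = 3.14e-05). Sln, the sarcolipin that inhibits the calcium pump of the sarcoplasmic reticulum, was at 363 CPM (SD 601) against 2.71 CPM (SD 0.741), with a log2 fold change of 7.06 (SE 1.23, adjusted p = 0.00216). This value rests on old wild type replicate 3 at 1260 CPM, with the other old wild type libraries at 40.6 to 81.4 CPM, and was 4.53 without it. Col3a1, a fibrillar collagen, was at 52.9 CPM (SD 16.1) against 339 CPM (SD 135), a log2 fold change of -2.68 (SE 0.45, adjusted p = 0.00154).

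At an adjusted p of 0.05, 1040 genes rose and 1151 fell with age in the wild type, of which 535 and 550 changed at least 2-fold. Krt8, the partner of Krt18, rose by 6.33 on the log2 scale (SE 0.88) and Ces2c, a carboxylesterase, by 5.06 (SE 0.53). Gdf5, a bone morphogenetic protein family member, rose from 0.0296 to 2.93 CPM and Glra3, a glycine receptor subunit, from 0.0106 to 2.17 CPM. Both young means lie below the level of 3 counts in these libraries (0.115 to 0.14 CPM), so the size of these rises is uncertain. Over the alternatives the log2 fold change ran from 5.58 to 9.39 for Gdf5 and from 4.44 to 8.67 for Glra3. The largest falls, among genes of at least 1 CPM whose libraries do not overlap between the groups, were those of Wif1, an inhibitor of Wnt signalling (log2 fold change -5.37, SE 0.88), Thbs1, thrombospondin 1 (-4.07, SE 0.40), Kera (-4.0, SE 0.95), Cilp2 (-3.80, SE 0.69), Adamts3 (-3.67, SE 0.71) and Col11a1 (-3.60, SE 0.73).

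Of 33 collagen and extracellular matrix genes, 22 fell and none rose (24 fell adjusted over the list alone), with a median log2 fold change of -1.51. Examples are Col5a2 (-1.90, SE 0.25), the matrix protein gene Sparc (-2.15, SE 0.34) and Lox, which cross-links collagen (-2.32, SE 0.36). The list was called by camera (adjusted p = 1.19e-11), and adjusted p = 0.591 with an estimated correlation. Of 15 fibroblast markers, 11 fell and none rose (12 fell adjusted over the list alone), among them Dpt (-1.38, SE 0.25) and Fbn1 (-2.28, SE 0.39). This list had adjusted p = 4.03e-08 by camera, and adjusted p = 0.436 with an estimated correlation. Of 12 tendon markers, 9 fell and none rose (10 adjusted over the list alone), with a median of -2.16 and Tnmd, tenomodulin, at -3.45 (SE 0.68). For the tendon list adjusted p = 1.05e-06, and adjusted p = 0.591 with an estimated correlation.

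Among 25 genes of denervation and the neuromuscular junction, 13 rose with age and none fell (14 adjusted over the list alone), with a median of 1.48. Gadd45a rose by 3.43 on the log2 scale (SE 0.57), from 15.1 to 163 CPM. Runx1 rose by 2.74 (SE 0.45) and Eda2r by 2.19 (SE 0.35). The list was called by camera (adjusted p = 2.76e-08), and adjusted p = 0.342 with an estimated correlation. Of 31 proteasome subunits, 13 rose and none fell (23 adjusted over the list alone), including Psmd3 (1.22, SE 0.23) and Psmb4 (0.93, SE 0.19). For the proteasome adjusted p = 6.93e-10, and adjusted p = 0.625 with an estimated correlation. Of 80 cytosolic ribosomal protein genes, 12 rose and none fell (17 adjusted over the list alone), among them Rpl10 (1.40, SE 0.36), Rplp2 (1.16, SE 0.32) and Rpl22l1 (1.56, SE 0.43). For these genes adjusted p = 1.33e-09, and adjusted p = 0.862 with an estimated correlation. Their mean was 0.182 to 0.824 in old wild type replicates 1 to 3 and -0.351 in replicate 4, and -0.575 to -0.376 in young wild type replicates 1 to 3 and 0.391 in replicate 4, as centred log2 CPM.

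Of 21 lipid synthesis genes, 6 fell and none rose (10 fell and 3 rose adjusted over the list alone), among them the sterol synthesis genes Sqle (-2.06, SE 0.36) and Hmgcs1 (-1.08, SE 0.24). Camera gave adjusted p = 0.0126, and adjusted p = 0.788 with an estimated correlation. Of 31 autophagy and lysosome genes, 7 rose and 1 fell, with the same counts adjusted over the list alone. Gabarapl1 rose by 0.90 (SE 0.17), while Ulk2 fell by 1.13 (SE 0.22). This list had adjusted p = 0.0427, and adjusted p = 0.788 with an estimated correlation. Among 22 antioxidant and NRF2 target genes 5 rose and none fell, also adjusted over the list alone, with catalase (Cat) at 0.75 (SE 0.18). The list had adjusted p = 0.0374, and adjusted p = 0.591 with an estimated correlation. Of 18 heat shock chaperones, 6 rose and 3 fell (6 and 5 adjusted over the list alone) and camera gave adjusted p = 0.399. The small heat shock proteins Hspb7 (2.46, SE 0.33) and Cryab (1.72, SE 0.38) rose and Dnaja1 fell by 1.02 (SE 0.18). Of 7 erythrocyte markers tested, 3 rose and none fell (6 adjusted over the list alone), with camera adjusted p = 0.16, and adjusted p = 0.862 with an estimated correlation. The mean of these markers was 1.56 in old wild type replicate 3 and -0.689 to -0.0155 in the other old wild type libraries.

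The test was edgeR's quasi-likelihood test with all 16 libraries in one fit. The counts were 526 higher and 635 lower without the 4 libraries with the highest lymphocyte markers, 342 and 557 without old wild type replicate 3 as well, 255 and 492 with the wild type groups fitted alone, and 1195 in all without young wild type replicate 2, 1323 without young wild type replicate 3 and 1282 without old wild type replicate 3.

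The third question was what changes with age in knockout muscle. Old knockout muscle, like old wild type muscle, had more RNA of Krt18 and Sln and less of 21 of 33 collagen and matrix genes, and it had less RNA of 10 of 37 subunits of complex I and of 9 of 16 adipocyte markers. Krt18 was at 11.3 CPM (SD 7.69, n = 4) in old against 0.0784 CPM (SD 0.0641, n = 4) in young knockout (log2 fold change 6.98, SE 0.84, adjusted p = 0.000305), and Sln at 176 CPM (SD 186) against 6.44 CPM (SD 3.02), a log2 fold change of 4.77 (SE 1.10, adjusted p = 0.0129). The old knockout libraries ran from 29.6 to 431 CPM for Sln, and its log2 fold change ran from 3.57 to 5.12 over the alternatives. Col3a1 was at 29.2 CPM (SD 24.1) against 438 CPM (SD 110), a log2 fold change of -3.90 (SE 0.47, adjusted p = 0.000305). Old knockout replicate 3 was at 65.3 CPM of Col3a1 and the other old knockout libraries at 16.1 to 18.8 CPM. Scd1, the stearoyl-CoA desaturase, was at 40.0 CPM (SD 11.6) against 352 CPM (SD 224), a log2 fold change of -3.14 (SE 0.42, adjusted p = 0.000532). Adipoq, the adipocyte hormone adiponectin, was at 5.63 CPM (SD 2.22) against 36.4 CPM (SD 19.1), a log2 fold change of -2.69 (SE 0.71, adjusted p = 0.0228).

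**Figure D3:**
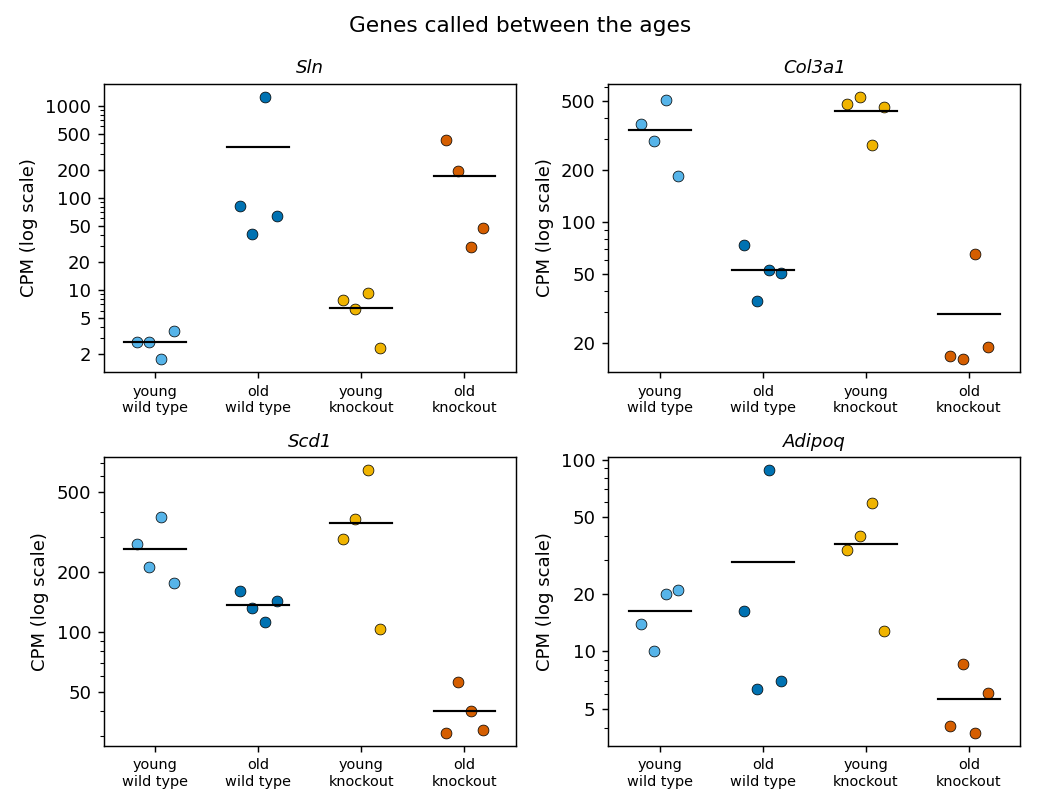
Levels of Sln, Col3a1, Scd1 and Adipoq in each library in CPM on a log scale. Points are single libraries and lines are group means (n = 4). Col3a1 has a mean of 339 CPM in young and 52.9 CPM in old wild type, and of 438 CPM in young and 29.2 CPM in old knockout.

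In the knockout 1127 genes rose and 912 fell with age, of which 441 and 480 changed at least 2-fold. Within the same limits of level and overlap, the largest rises besides Krt18 and Sln were those of Ggt6 (4.69, SE 0.75), Cpn1 (4.52, SE 0.67), Tmem132b (4.47, SE 0.62) and Krt8 (3.88, SE 0.81). The largest falls were those of Mup22 (-5.68, SE 1.14), Wif1 (-5.53, SE 0.95), Aldh1a7 (-4.54, SE 0.59), Nrk (-4.40, SE 0.90), Col1a1, the chain of collagen I (-3.97, SE 0.64), and Nrep (-3.96, SE 0.54).

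Of 33 collagen and extracellular matrix genes, 21 fell with age in the knockout and none rose (27 fell adjusted over the list alone), with a median of -1.56. Sparc fell by 2.63 (SE 0.34) and Serpinh1, the collagen chaperone, by 1.79 (SE 0.21). The matrix list had adjusted p = 4.25e-17, and adjusted p = 0.494 with an estimated correlation. Of 15 fibroblast markers 7 fell and none rose (9 fell and 1 rose adjusted over the list alone), with Dpt at -1.77 (SE 0.25). The fibroblast list had adjusted p = 2.39e-06, and adjusted p = 0.494 with an estimated correlation. Of 12 tendon markers 5 fell and none rose (6 adjusted over the list alone), with Tnmd at -3.19 (SE 0.69) and Cilp2 at -3.52 (SE 0.67). For them adjusted p = 9.86e-05, and adjusted p = 0.658 with an estimated correlation.

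Of 25 denervation and neuromuscular junction genes, 11 rose and none fell (14 adjusted over the list alone), with a median of 1.19. The acetylcholine receptor subunit genes Chrnb1 (2.17, SE 0.35) and Chrnd (2.18, SE 0.43) rose, as did Myh3, the embryonic myosin (3.40, SE 0.60, from 3.65 to 38.5 CPM). The denervation list had adjusted p = 2.39e-06, and adjusted p = 0.494 with an estimated correlation. Of 31 proteasome subunits, 10 rose and none fell (12 adjusted over the list alone), with Psmc2 at 0.82 (SE 0.21) and Psmd8 at 0.84 (SE 0.19). The proteasome list had adjusted p = 0.00257, and adjusted p = 0.87 with an estimated correlation. Of 31 autophagy and lysosome genes, 9 rose and none fell (11 adjusted over the list alone), including Ulk1, which starts autophagy (1.53, SE 0.40), and Lamp1 (0.68, SE 0.16). For autophagy adjusted p = 0.00318, and adjusted p = 0.658 with an estimated correlation. Of 18 heat shock chaperones 7 rose and 1 fell, also adjusted over the list alone, with Hsp90ab1 at 1.01 (SE 0.22) and Dnaja1 at -0.91 (SE 0.18). This list had adjusted p = 0.0179, and adjusted p = 0.658 with an estimated correlation.

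Of 37 subunits of respiratory complex I, 10 fell with age in the knockout and none rose (13 fell and 1 rose adjusted over the list alone), with a median of -0.36. Ndufb2 fell by 1.23 (SE 0.25) and Ndufa5 by 0.95 (SE 0.20). Camera gave adjusted p = 6.76e-05, and adjusted p = 0.84 with an estimated correlation. Of 42 subunits of complexes II to V, 8 fell and none rose (14 adjusted over the list alone), with Atp5k at -3.06 (SE 0.74) and Uqcr11 at -1.61 (SE 0.44). For complexes II to V adjusted p = 0.000272, and adjusted p = 0.84 with an estimated correlation. The 13 mitochondrial DNA transcripts had a median of 0.14, with none called (adjusted p = 0.868, and adjusted p = 0.967 with an estimated correlation). Of 78 mitochondrial ribosomal proteins 12 fell and 2 rose (14 and 2 adjusted over the list alone), with Mrps21 at -0.94 (SE 0.25) and Mrps18b at 1.0 (SE 0.19). For them adjusted p = 0.0038, and adjusted p = 0.877 with an estimated correlation. The level of Rps29, chosen after its values were seen, was at 84.1 to 148 CPM in the young and 31.2 to 87.1 CPM in the old knockout libraries.

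Of 16 adipocyte markers, 9 fell and 1 rose with age in the knockout (11 and 2 adjusted over the list alone), with a median of -2.18. Leptin (Lep) fell by 3.01 (SE 0.74) and Pck1, the enzyme of glyceroneogenesis, by 3.28 (SE 0.79). The list had adjusted p = 0.000383, and adjusted p = 0.792 with an estimated correlation. Of 21 lipid synthesis genes 3 fell and none rose (7 fell and 1 rose adjusted over the list alone), with Thrsp at -1.97 (SE 0.24). These genes had adjusted p = 0.0363, and adjusted p = 0.84 with an estimated correlation. Of 14 slow fibre proteins 2 rose and none fell (3 adjusted over the list alone): the slow myosin Myh7 (1.90, SE 0.56) and the slow calcium pump Atp2a2 (1.32, SE 0.32). The slow fibre list had adjusted p = 0.0179, and adjusted p = 0.84 with an estimated correlation. Among fast fibre proteins, parvalbumin (Pvalb) fell by 1.86 (SE 0.35) and the fast calcium pump Atp2a1 rose by 1.2 (SE 0.31). Of 22 antioxidant and NRF2 targets 4 rose and none fell (9 rose and 1 fell adjusted over the list alone), with Gpx3 at 1.48 (SE 0.25). For them adjusted p = 0.0363, and adjusted p = 0.531 with an estimated correlation. Of 11 myokines and secreted muscle factors 4 fell and none rose (4 fell and 1 rose adjusted over the list alone), with Fstl1 at -1.86 (SE 0.23). Camera gave adjusted p = 0.0179 for myokines, and adjusted p = 0.531 with an estimated correlation.

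The counts with age in the knockout were 1150 higher and 934 lower without the 4 libraries with the highest lymphocyte markers, 1848 and 1459 without old wild type replicate 3 as well, and 2713 and 2553 by limma-voom. In all, 578 genes were called without young knockout replicate 2, 772 without old knockout replicate 2, 792 without young knockout replicate 1 and 1210 without old knockout replicate 3. Sln was not called without young knockout replicate 2 (adjusted p = 0.051), and the call of Adipoq was lost in 5 of 30 alternatives.

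The age responses of the genotypes were then compared over the same genes. Of the genes called with age, 335 rose and 378 fell in both genotypes, where 80.4 and 72 would be shared if the calls were independent, and 11 were called in opposite directions. Both comparisons share the spread of each gene, so a gene easy to call in 1 is easy to call in the other. More than 80.4 and 72 can thus be shared without a common response. The same ease would raise opposite calls as well, of which there were 11. Across the 14579 genes the age fold changes had Pearson r = 0.479 and Spearman rho = 0.452, and genes are not independent replicates. Of the genes called in the wild type 86.7% had the same sign in the knockout, and 85.7% of those called in the knockout had the same sign in the wild type, against 66.1% of all genes. The matrix, tendon and denervation lists had medians of the same sign in both genotypes, whereas the ribosomal protein list had medians of 0.57 in the wild type and -0.12 in the knockout. The adipocyte list had medians of 0.64, not called in the wild type (adjusted p = 0.401), and -2.18. Its mean, as centred log2 CPM, was 1.80 in old wild type replicate 3, and -0.874 to 0.0815 in the other old and -0.609 to 0.376 in the young wild type libraries.

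**Figure D4:**
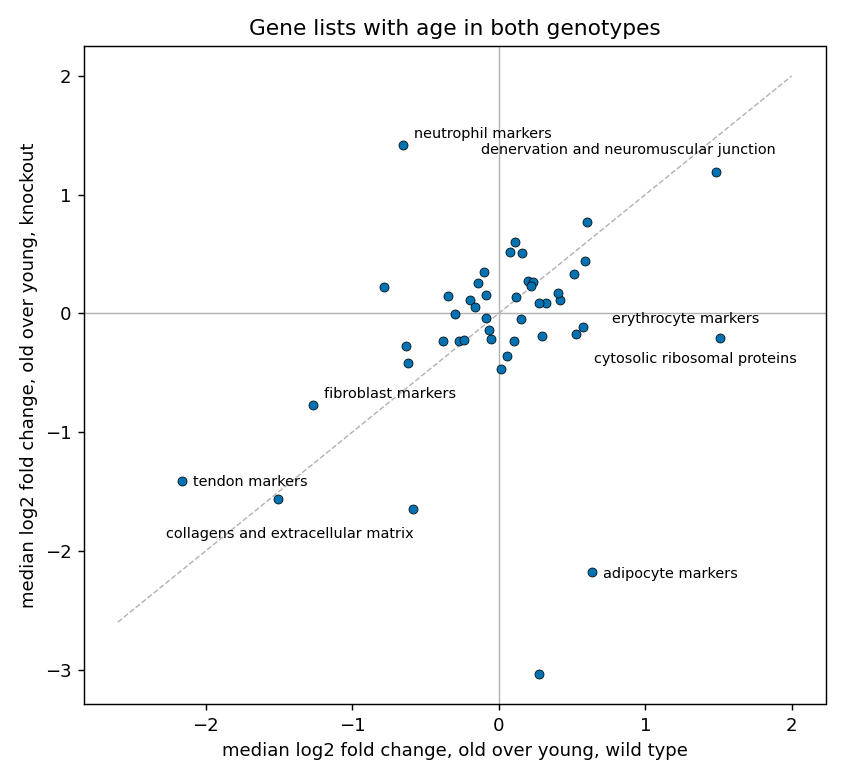
Median log2 fold change between old and young muscle of each of the 46 gene lists, in wild type (horizontal axis) and in knockout (vertical axis), with the line of equality dashed. Collagens and extracellular matrix lie at -1.51 and -1.56, denervation and neuromuscular junction at 1.48 and 1.19, and adipocyte markers at 0.64 (not called, with old wild type replicate 3 above the other wild type libraries) and -2.18.

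The fourth question was what the knockout changes at 2 months. Young knockout muscle had less RNA of Nadsyn1, of thrombospondin 1 and of 6 of 21 immediate early genes, the transcription factors that cells switch on within minutes of a stimulus. Thbs1 was at 19.2 CPM (SD 8.33, n = 4) in young knockout and 190 CPM (SD 89.8, n = 4) in young wild type (log2 fold change -3.31, SE 0.38, adjusted p = 0.000717). The AP-1 members Fosb (-4.86, SE 0.86, adjusted p = 0.0156) and Junb (-3.48, SE 0.51, adjusted p = 0.00351) were lower as well. Adora1, the adenosine A1 receptor, was higher, at 13.6 CPM (SD 5.14) against 2.43 CPM (SD 0.257), a log2 fold change of 2.49 (SE 0.39, adjusted p = 0.00703).

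In young muscle 21 genes were higher and 53 lower in the knockout. Besides Nadsyn1, Thbs1, Fosb and Junb, the lower genes of largest change within the same limits of level and overlap include Ccl7, a chemokine (-4.31, SE 0.93), and Apold1 (-3.21, SE 0.59). The higher ones besides Adora1 include Adra2b, an adrenergic receptor (2.96, SE 0.53), Tril (2.05, SE 0.36), Trarg1 (1.86, SE 0.33), the alcohol dehydrogenase Adh1 (1.37, SE 0.25) and Neurl1b (1.30, SE 0.27). Of 21 immediate early genes 6 were lower and none higher (13 lower adjusted over the list alone), with a median of -1.73. They include Nr4a3, a nuclear receptor induced by exercise, at 11 against 85.1 CPM (-2.96, SE 0.50), and Fosl2 (-2.34, SE 0.35). Camera gave adjusted p = 1.24e-13 for this list, and adjusted p = 0.281 with an estimated correlation. The list mean, as centred log2 CPM, was 1.45 and 1.75 in young wild type replicates 1 and 3, 0.191 and -0.0736 in replicates 2 and 4, and -0.919 to -0.605 in young knockout.

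Single members of other lists were called too. The sterol genes Sqle (-1.86, SE 0.36) and Insig1 (-0.91, SE 0.20) were lower, as was Btg2 (-1.88, SE 0.38) of the p53 and senescence list. The chaperone Hsp90aa1 was lower (-1.0, SE 0.19), with 1 of 18 heat shock genes called (5 adjusted over the list alone). That list had adjusted p = 0.033, and adjusted p = 0.737 with an estimated correlation. The clock gene Per3 (1.13, SE 0.21), Dok7 of the neuromuscular junction (1.0, SE 0.16) and the growth factor gene Igf2 (0.97, SE 0.21) were higher.

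Further lists were called by camera at 2 months with no gene called, or with 1. Respiratory complex I (37 genes, median 0.27), complexes II to V (42 genes, 0.34), cytosolic ribosomal proteins (80 genes, 0.26), mitochondrial ribosomal proteins (78 genes, 0.19) and fatty acid oxidation (29 genes, 0.30, with 3 higher adjusted over the list alone) had positive medians, with adjusted p between 3.95e-07 and 1.95e-06, and adjusted p between 0.737 and 0.913 with an estimated correlation. Rps29 was at 84.1 to 148 CPM in young knockout, 27.6 to 32.0 CPM in young wild type replicates 1 to 3 and 104 CPM in replicate 4. Young wild type replicate 4 also had a complex I mean of 0.41 and a ribosomal mean of 0.391, against at most -0.0993 and -0.376 in replicates 1 to 3, and 0.191 to 0.361 and -0.0445 to 0.145 in young knockout. Adipocyte (16 genes, 0.83) and erythrocyte markers (7 genes, 1.05) had positive medians too, with adjusted p = 0.000423 and 0.000797, and for both adjusted p = 0.737 with an estimated correlation. Immune lists had negative medians: inflammatory cytokines and complement (-0.81, 1 of 22 called and 4 adjusted over the list alone), interferon-stimulated genes (-0.49, 1 of 26 adjusted over the list alone), macrophage (-0.95, 1 of 16 adjusted over the list alone), neutrophil (-1.65), T and natural killer (-2.04) and B and plasma cell markers (-2.01). Their adjusted p ran from 6.98e-05 to 0.0422, and was 0.737 to 0.924 with an estimated correlation. Young wild type replicates 1 and 4 and young knockout replicate 3 are the young libraries with high lymphocyte markers. The 13 mitochondrial DNA transcripts had a median of -0.44 (adjusted p = 0.0464, and adjusted p = 0.924 with an estimated correlation).

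At 2 months the counts were 1 higher and 25 lower without the 4 libraries with the highest lymphocyte markers and 35 and 168 without old wild type replicate 3 as well. DESeq2 called 102 higher and 178 lower, limma-voom 860 and 768, and between 27 genes (without young knockout replicate 4) and 139 (without young wild type replicate 4) were called when 1 library was left out. Among 30 alternatives the calls of Nadsyn1, Thbs1, Junb and Fosl2 were kept in each, those of Igf2, Insig1, Ccl7 and Neurl1b were lost in 21, 20, 15 and 14, and those of Btg2 and Per3 in 9. With unique exon reads Adora1 had adjusted p = 0.393, Igf2 0.48 and Per3 0.359.

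The fifth question was what the knockout changes at 24 months. No gene passed edgeR's test between old knockout and old wild type, with a smallest adjusted p of 0.0928. At an unadjusted p of 0.05 there were 2078 genes, where chance would give 729 on average. Genes that move together between libraries can carry such a count far from that average without an effect of genotype. It was not counted for other groupings of the libraries, of which the highest called 63 genes by edgeR at an adjusted p of 0.05. DESeq2 called 68 higher and 183 lower and limma-voom 2 higher and 3 lower. The gene of the knockout, Nadsyn1, was at -2.48 (SE 0.46, adjusted p = 0.105). Junb was at 7.74 against 38.1 CPM (-2.30, SE 0.48, adjusted p = 0.112) and Fosl2 at 14.7 against 36.3 CPM (-1.31, SE 0.35, adjusted p = 0.171). Scd1 had a log2 fold change of -1.77 (SE 0.40, adjusted p = 0.15), Adrb3, the adipocyte adrenergic receptor, one of -3.48 (SE 0.79, adjusted p = 0.15) and Dok7 one of 0.71 (SE 0.16, adjusted p = 0.143).

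Camera called 12 lists at 24 months. Cytosolic ribosomal proteins (80 genes, median -0.42, for example Rpl22l1 at -1.69, SE 0.43) had adjusted p = 1.42e-09, and adjusted p = 0.961 with an estimated correlation, which was also the value of the other 11 lists. The ribosomal mean was -0.351 in old wild type replicate 4 and 0.182 to 0.824 in replicates 1 to 3, and Rps29 was at 28.4 CPM in replicate 4 and 182 to 263 CPM in the others. Proteasome subunits (31 genes, -0.25, Psmb5 at -0.87, SE 0.25) had adjusted p = 0.000197, as did glycolysis and glycogen (29 genes, 0.35, Gpi1 at 0.56, SE 0.16) and the tricarboxylic acid cycle (23 genes, 0.32, Idh2 at 0.87, SE 0.31). Old wild type replicate 3 was below the other old wild type libraries in the list means of glycolysis (-0.776, others -0.136 to 0.0677), the tricarboxylic acid cycle (-0.876, others -0.262 to 0.362), biogenesis regulators (-0.815, others -0.179 to 0.119) and slow fibre proteins (-0.747, others 0.327 to 0.468). Adipocyte markers had a median of -1.76 (8 of 16 lower and 1 higher adjusted over the list alone, adjusted p = 0.0012), and immediate early genes one of -0.64 (4 of 21 lower adjusted over the list alone, adjusted p = 0.00126). B and plasma cell markers had a median of -4.88 (8 of 8 lower adjusted over the list alone, adjusted p = 0.00157), with old wild type replicates 1 and 3 high in lymphocyte markers and no old knockout library. Adipoq was at 87.7 CPM in old wild type replicate 3 and at 6.35 to 16.2 CPM in the other old wild type libraries. Endoplasmic reticulum stress (-0.21), p53 and senescence (-0.34) and antigen presentation (-0.85) had negative medians, and regulators of mitochondrial biogenesis (0.33) and slow fibre proteins (0.54) positive ones, with adjusted p from 0.0177 to 0.0222.

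Without old wild type replicate 4, 62 genes were higher and 160 lower at 24 months, and 228 and 376 without young wild type replicate 4 as well. Without the 4 libraries with the highest lymphocyte markers none was called, and without old wild type replicate 3 as well 2 of the 12 lists were still called. In that setting 2 lists of genotype at 24 months turned: antigen presentation was called as higher (adjusted p = 0.000119) and the tricarboxylic acid cycle was lower but not called (adjusted p = 0.597).

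The last question was whether the age response differed between genotypes. The genes called include Ugdh, Gfpt2 and Thbs1, whose levels were high in young wild type muscle and low in the other 3 groups. Ugdh, which makes UDP-glucuronate, was at 68.9 CPM (SD 12.6, n = 4) in young wild type, 6.67 CPM (SD 1.40) in old wild type, 10.2 CPM (SD 2.70) in young knockout and 6.60 CPM (SD 0.822) in old knockout (interaction 2.73 on the log2 scale, SE 0.30, adjusted p = 0.000826). Gfpt2, an enzyme of hexosamine synthesis, was at 64.1 CPM (SD 25.9), 6.10 CPM (SD 2.22), 7.11 CPM (SD 1.81) and 10.1 CPM (SD 1.18) in the same groups (interaction 3.90, SE 0.44, adjusted p = 0.000826). Thbs1 had an interaction of 3.26 (SE 0.51, adjusted p = 0.0211), with 11.3 CPM (SD 2.08) in old wild type and 10.9 CPM (SD 3.44) in old knockout.

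**Figure D5:**
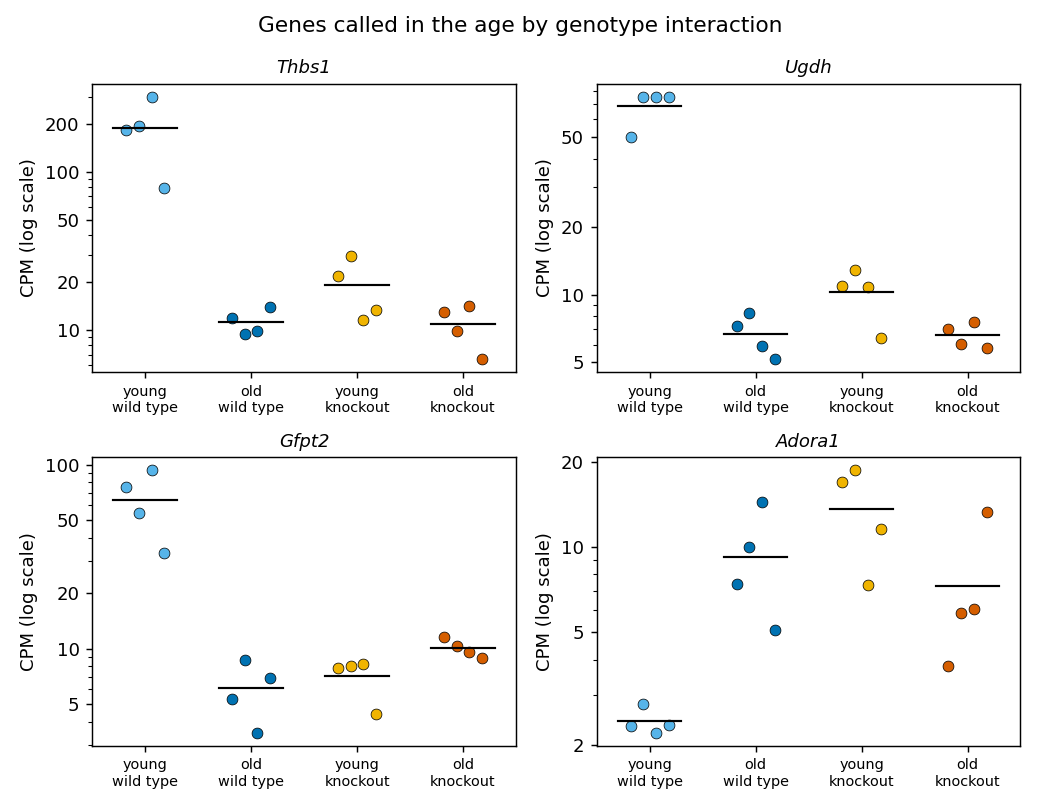
Levels of Thbs1, Ugdh, Gfpt2 and Adora1 in each library in CPM on a log scale. Points are single libraries and lines are group means (n = 4). Ugdh has a mean of 68.9 CPM in young wild type and of 6.67, 10.2 and 6.60 CPM in old wild type, young knockout and old knockout.

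The interaction was called for 21 genes, with 8 positive (a higher response to age in the knockout) and 13 negative. Irak3, an inhibitor of innate immune signalling (2.05, SE 0.31), and Rapgef5 (1.70, SE 0.25) were positive too. Negative were Aldh1a7 (-3.97, SE 0.74), Rpl22l1 (-3.21, SE 0.61), Adora1 (-2.84, SE 0.54), the copper chaperone gene Cox17 (-1.99, SE 0.37) and Pfdn2, a prefoldin subunit (-1.77, SE 0.32). Aldh1a7 was at 2.22 CPM (SD 0.292) in young and 0.0897 CPM (SD 0.0881) in old knockout, and at 1.53 CPM (SD 0.446) and 1.01 CPM (SD 0.514) in young and old wild type. Its mean in old knockout lies below the level of 3 counts there (0.145 to 0.163 CPM), so the size of its fall is uncertain. Cox17 was at 26.4 CPM (SD 9.99) in young and 53.1 CPM (SD 17.9) in old wild type, and at 47.6 CPM (SD 7.13) and 24.1 CPM (SD 4.36) in young and old knockout.

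Of 80 cytosolic ribosomal protein genes 1 was called, lower, in the interaction (17 adjusted over the list alone), with a median of -0.72. The list had adjusted p = 1.05e-13, and adjusted p = 0.926 with an estimated correlation, which was the value of all 9 lists that camera called here. The ribosomal mean was 0.391 in young wild type replicate 4 (others -0.575 to -0.376) and -0.351 in old wild type replicate 4 (others 0.182 to 0.824), while the complex I mean was 0.41 in young wild type replicate 4 (others -0.357 to -0.0993). Complex I (37 genes, median -0.39, 13 lower and 1 higher adjusted over the list alone, adjusted p = 7.57e-06) held Ndufa3 (-1.92, SE 0.42, adjusted p = 0.0761) and Ndufa5 (-1.29, SE 0.28, adjusted p = 0.073). Complexes II to V (-0.44, 7 of 42 lower adjusted over the list alone, adjusted p = 0.000147), mitochondrial ribosomal proteins (-0.25, adjusted p = 2.19e-05) and proteasome subunits (-0.20, 1 of 31 lower adjusted over the list alone, adjusted p = 0.0061) had negative medians too. Adipocyte markers had a median of -2.41 (10 of 16 lower adjusted over the list alone, adjusted p = 7.57e-06), with Adrb3 at -4.55 (SE 1.05, adjusted p = 0.0874) and with old wild type replicate 3 above the other wild type libraries in the list mean (1.80). Immediate early genes (1.0, 2 of 21 higher adjusted over the list alone, adjusted p = 0.00383), neutrophil markers (2.22, adjusted p = 0.0153) and the tricarboxylic acid cycle (0.32, adjusted p = 0.0215) had positive medians. The neutrophil mean was 1.97 and 1.64 in young wild type replicates 1 and 4, which are high in lymphocyte markers, and -1.27 and -0.26 in replicates 2 and 3, and the tricarboxylic acid cycle mean was -0.876 in old wild type replicate 3 (others -0.262 to 0.362). Nr4a3 was at 2.32 (SE 0.69, adjusted p = 0.151).

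The interaction count was 3 without the 4 libraries with the highest lymphocyte markers, 20 without old wild type replicate 3 as well, 527 without old wild type replicate 4, 403 without young wild type replicate 4 and 2 without young knockout replicate 1. The calls of Adora1, Aldh1a7, Cox17, Pfdn2 and Rpl22l1 were lost in 16 to 18 of the 29 alternatives, for example without young wild type replicate 2, those of Thbs1, Rapgef5 and Irak3 in 6, 4 and 3, while those of Gfpt2 and Ugdh were kept in each of the 29.

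The authors' own test, with its adjusted p in the deposited table, called 626 genes higher and 775 lower with age in the wild type, 641 and 573 with age in the knockout, 30 and 79 in the knockout at 2 months and 8 and 36 in the knockout at 24 months. Of these, 1334, 1165, 70 and 0 were also called here. Nadsyn1 had a signed fold change of -10.9 (adjusted p = 2.51e-07) at 2 months and of -5.53 (adjusted p = 0.00442) at 24 months in that table.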

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

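The tests of a knockout effect alike at both ages, of blood, of age or genotype as the source of lymphocyte markers, and of exchanged labels were chosen only after their results were seen. Among 108 combinations of a group and a measure, 12 held a library far from the other 3 of its group (a gap, relative to the range, above Dixon's 95% critical value), where chance gives about 1 in 20 for independent normal values. Some of these measures move together, and Rps29 was chosen after its values were seen. The count of 12 is therefore no test against chance.

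Young wild type replicate 4 had 26462502 exon reads, against 24003086 to 24366552 in the others of its group. Young wild type replicate 2 had 17117 genes detected, against 18013 to 18109. Young knockout replicate 3 had a lymphocyte marker mean of 2.71, against -1.75 to -1.67. Krt18 was at 0.174 CPM in young knockout replicate 1, against 0.0406 to 0.0519 CPM, and Krt8 at 3.54 CPM in old knockout replicate 1, against 0.509 to 0.966 CPM. These Krt18 values rest on few reads, as 3 counts equal 0.105 to 0.156 CPM in young knockout. Sln was at 1260 CPM in old wild type replicate 3, against 40.6 to 81.4 CPM. Adipoq was at 87.7 CPM in the same library, against 6.35 to 16.2 CPM. Col3a1 was at 65.3 CPM in old knockout replicate 3, against 16.1 to 18.8 CPM. Ugdh was at 50.0 CPM in young wild type replicate 1, against 75.0 to 75.5 CPM, and Gfpt2 at 4.40 CPM in young knockout replicate 4, against 7.81 to 8.21 CPM. In young wild type replicate 4 Rpl22l1 was at 20.6 CPM, against 8.69 to 9.52 CPM, and Rps29 at 104 CPM, against 27.6 to 32.0 CPM.

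The age response differed between genotypes, by the interaction test, for 21 genes. On the log2 scale the interaction was 3.90 for Gfpt2, 3.26 for Thbs1, 2.73 for Ugdh, 2.05 for Irak3 and 1.70 for Rapgef5, and it was -3.97 for Aldh1a7, -3.21 for Rpl22l1, -2.84 for Adora1, -1.99 for Cox17 and -1.77 for Pfdn2. Among lists the interaction had an adjusted p by camera of 1.05e-13 for cytosolic ribosomal proteins, 7.57e-06 for complex I and for adipocyte markers, 2.19e-05 for mitochondrial ribosomal proteins, 0.000147 for complexes II to V, 0.00383 for immediate early genes, 0.0061 for proteasome subunits, 0.0153 for neutrophil markers and 0.0215 for the tricarboxylic acid cycle, with an adjusted p = 0.926 for each with an estimated correlation. As many genes as the 21 were called in 5 of 100 drawn groupings of the libraries, the real one included, and the highest other grouping gave 161, so chance is not excluded for this count. A count several times the real one points to a structure of the libraries, and what that grouping follows was not tested.

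In the same count of groupings, the real one called the most genes for age in the wild type (1 of 35, with 2191 genes against 715 in the highest other). The same held for age in the knockout (1 of 35, 2039 against 0) and for genotype at 2 months (1 of 35, 74 against 0). With 35 groupings no smaller share is possible. The other groupings mix the compared groups, which can widen the spread within them. These counts therefore make chance less likely but do not exclude it. The grouping that gave 715 exchanges young wild type replicate 4 and old wild type replicate 4, and the next, with 645 genes, puts the 4 wild type libraries with high lymphocyte markers together. For genotype at 24 months the real count by edgeR is 0 (2078 genes at an unadjusted p under 0.05, 251 called by DESeq2 and 5 by limma-voom), so that each of the 35 groupings gives at least as many and the comparison tells nothing. The highest other gave 63.

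Reads in introns were not used in the comparisons. Among 11507 genes they called 1367 with age in the wild type, of which 480 were also called from exon reads, 178 with age in the knockout (76 also), 199 for genotype at 2 months (19 also) and 52 in the interaction (3 also). At 24 months 0 were called by edgeR from intron reads, with 1102 at an unadjusted p under 0.05, and no other tool was run on them.

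The 53 genes lower in young knockout than in young wild type had a median log2 fold change of -1.76. With the lymphocyte marker mean as a covariate their median was -1.76 (bootstrap SD 0.15 over resampled genes, range -5.94 to -0.82) and 51 were still called. The fold changes of these genes thus did not follow that mean. The markers vary within the young groups, and a gene that follows them is hard to call. Of 8 B and plasma cell and 10 T and natural killer cell markers, 0 were called at 2 months. The test on called genes could hardly come out otherwise, so no conclusion on lymphoid tissue is drawn from it. Handling or dissection of the young wild type mice stays open: over the 12 libraries of the other groups, the 47 genes not on the immediate early list followed that list within groups with Pearson r = 0.0219 (permutation p = 0.96) and Spearman rho = 0.294 (permutation p = 0.409), and r was 0.234 without the 2 farthest libraries, in the 1 relation of this kind that was computed. A knockout effect on immediate early genes alike at both ages stays open too. With an estimated correlation their interaction had p = 0.17, and genotype at 24 months had p = 0.14. Their medians were -1.73 at 2 months and -0.64 at 24 months, and camera with the preset correlation called the interaction (adjusted p = 0.00383). These 2 explanations cannot be told apart here, because few libraries carry the list and the labels give nothing on how the mice were handled.

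The pooled mean of lymphocyte markers was high in 5 libraries and low in 11, with the B cell gene Cd79a at 2.19 to 28.6 CPM in the former and at most 0.218 CPM in the latter, while the T cell gene Cd3e overlapped (0.499 to 5.54 against 0.26 to 2.51 CPM) and T and natural killer cell markers were not high in old wild type replicate 3 (mean 0.179, against 0.217 in old knockout replicate 4). Of the 4 groups 3 hold libraries of both kinds, which argues against age or genotype of the mice as the whole cause. Blood left in the muscle is argued against as the whole source in 4 of the 5, where the lymphocyte marker mean lay 4.43 to 5.61 above the median of the low libraries of the same group (log2) and the erythrocyte marker mean lay -0.755 to 0.446 from it (SD 0.40 within groups). Lymph node tissue taken with the muscle may be a source: of 7 genes of lymph node stroma and vessels, of which Ccl21a, Ccl19 and Cxcl13 had reads in every other library too and Cr2 in some, 3 were higher in each of the 5 libraries than in every other one, namely Glycam1 (0.914 to 22.5 CPM against 0), Ccl19 (1.97 to 14.7 against 0.141 to 0.571) and Ccl21a (12.9 to 59.6 against 2.57 to 11.5). In old wild type replicate 3 the lymphocyte marker mean lay 2.67 and the erythrocyte marker mean 2.02 above that median, so for this library lymph node tissue and blood cannot be told apart, as 1 library and the SD leave both open.

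The 80 cytosolic ribosomal protein genes had a median interaction of -0.72. With the trend of gene length and GC content removed from each library it was -0.55 (bootstrap SD 0.061 over resampled genes, camera adjusted p = 1.3e-09), so a part played by this trend stays open. The genes of this list move together (estimated correlation 0.708), so this SD does not measure the spread between libraries. Exchanged labels of young wild type 4 and old wild type 4 are argued against, since 0 of these 2 libraries lay nearer to the other age in the genes called with age in the knockout (means -0.60 and 0.43, against -0.29 and 0.25 for the other young and old wild type libraries). A movement of the whole list between libraries that has no tie to the groups is consistent with an exact permutation p = 0.0535 over 4900 arrangements, two-sided. A difference in age response between genotypes stays among the open explanations, as untested by these values.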

How the results depend on the processing

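Unique exon reads, leaving out libraries by their lymphocyte markers, leaving out the fourth young and old wild type libraries, the lymphocyte covariate and the length and GC correction were chosen after the data were seen. Counts are given as genes higher and genes lower. The cause of each change was not tested, apart from a further minimum on the fold change, which can only lower a count. Fewer libraries can lower a count too. Leaving out 1 library also raised some counts, so it matters which library is left out. Alternatives other than leaving out 1 library kept each count within 1.5 times where they are not named. For leaving out 1 library the range is given, with the totals that moved by more than 1.5 times.

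With age in the wild type (1040 and 1151), the counts were 255 and 492 with the groups compared alone, 526 and 635 without the 4 libraries with the highest lymphocyte markers, 342 and 557 without old wild type replicate 3 as well, and 535 and 550 at a log2 fold change of at least 1. With age in the knockout (1127 and 912) they were 2713 and 2553 by limma-voom, 1839 and 1699 with the groups compared alone, 1848 and 1459 without these 5 libraries, and 441 and 480 at a log2 fold change of at least 1. The main fit shares the estimate of the spread of each gene over all groups. Libraries correlated less within the wild type groups (median 0.945 and 0.929) than within the knockout groups (0.968 and 0.968). The main counts therefore do not compare the size of the age response between genotypes. Leaving out 1 library gave 512 to 1285 higher and 683 to 1374 lower in the wild type and 305 to 1449 higher and 273 to 1253 lower in the knockout. The total was more than 1.5 times lower without young wild type replicate 2 (1195) or 3 (1323) or old wild type replicate 3 (1282) in the wild type, and without young knockout replicate 1 (792) or 2 (578) or old knockout replicate 2 (772) or 3 (1210) in the knockout. The overlap of age responses, 713 genes, was 143 at an adjusted p under 0.01 and 1295 under 0.1.

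For genotype at 2 months (21 and 53) the counts were 102 and 178 by DESeq2, 860 and 768 by limma-voom, 67 and 112 with the groups compared alone, 1 and 25 without the 4 libraries, 35 and 168 without the 5, and 283 and 163 without the fourth young and old wild type libraries. Higher genes alone moved to 32 with a filter of 1 CPM, to 13 with unique exon reads and to 32 with the length and GC correction. Leaving out 1 library gave 8 to 55 higher and 19 to 84 lower, in all 35 without young wild type replicate 3, 31, 43, 41 and 27 without young knockout replicates 1, 2, 3 and 4, 139 without young wild type replicate 4 and 122 without old wild type replicate 3. For genotype at 24 months (0 and 0 by edgeR, with 2078 genes at an unadjusted p under 0.05) the counts were 68 and 183 by DESeq2, 2 and 3 by limma-voom, and 228 and 376 without the fourth young and old wild type libraries. Leaving out 1 library gave 0 to 62 higher and 0 to 160 lower, with 222 genes in all without old wild type replicate 4, 2 without young wild type replicate 4, 1 without old wild type replicate 2, 1 without old knockout replicate 3 and 0 without any other library.

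For the interaction (8 and 13) the counts were 112 and 243 by DESeq2, 456 and 599 by limma-voom, 13 and 22 with no filter, 3 and 0 without the 4 libraries, 17 and 3 without the 5, 558 and 771 without the fourth young and old wild type libraries, 15 and 24 with the lymphocyte covariate and 22 and 42 with the length and GC correction. Higher genes moved to 13 with a filter of 1 CPM, and lower genes to 5 with upper-quartile factors, where 54.5% of the calls were higher against 38.1% in the main test. Leaving out 1 library gave 2 to 182 higher and 0 to 345 lower, in all 527 without old wild type replicate 4 and 403 without young wild type replicate 4. The total was 7, 9 and 6 without young wild type replicates 1, 2 and 3, 4 without old wild type replicate 1, 2, 6 and 7 without young knockout replicates 1, 2 and 4, and 6, 9 and 3 without old knockout replicates 1, 2 and 3.

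With a replicate block the counts were 743 and 1004 with age in the wild type, 828 and 750 with age in the knockout, 15 and 32 for genotype at 2 months, 0 and 0 at 24 months and 3 and 0 in the interaction. The residuals gave no pairing by replicate number common to all groups. Over 24 pairs of groups and numbers their correlation ran from -0.455 to 0.558, and 9 pairs exceeded 0.1. Of 16 libraries 5 correlated best with one of their own number. Young and old wild type had 0.558 and 0.435 for replicates 1 and 2, and -0.00807 and -0.33 for replicates 3 and 4. These values cannot exclude a pairing that the labels do not state.

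Named genes kept their direction in each alternative, apart from Nnt at 2 months, whose log2 fold change of -0.06 was 0.012 with the length and GC correction, and with 1 library left out ran from -0.19 (without young wild type replicate 4) to 0.073 (without young wild type replicate 2), with 0.016 without young knockout replicate 2. Of the called genes named, 32 of 51 with age in the wild type, 33 of 51 with age in the knockout, 4 of 21 at 2 months and 2 of 10 in the interaction were called in each alternative. Of the lists called by camera, 6 of 10 with age in the wild type, 11 of 15 with age in the knockout, 11 of 16 at 2 months, 4 of 12 at 24 months and 5 of 9 in the interaction were called with each library left out in turn. In 4 cases the direction of a list turned: T and natural killer cell markers for genotype at 2 months (adjusted p = 0.892 with the lymphocyte covariate), and for genotype at 24 months the tricarboxylic acid cycle (0.597 without the 5 libraries) and antigen presentation (0.000119 without the 5 libraries and 0.522 with the lymphocyte covariate). The covariate is itself made from the T and natural killer and the B and plasma cell lists. It takes out their own signal, so the value of 0.892 is no test of that list. At 18560480 to 28152454 exon reads per library, recovery of simulated 2-fold changes was 30% to 33% in the comparisons of groups and 9% in the interaction.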

Other observations

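The genes of single libraries and the intron reads of Nadsyn1 below were looked at after the data were seen.

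Clock genes differed between ages in wild type muscle. Of 18 circadian clock genes 7 rose and 1 fell (8 and 4 adjusted over the list alone), with camera adjusted p = 0.0497, and adjusted p = 0.788 with an estimated correlation. The repressors Per2 (log2 fold change 2.00, SE 0.27), Cry2 (1.66, SE 0.27) and Per3 (1.52, SE 0.21) rose and Clock fell by 1.34 (SE 0.23). The calls of Per2 and Cry2 were kept in each of 30 alternatives. That of Per3 was lost in 1, unique exon reads (adjusted p = 0.0922), and that of Clock in 1, without the 5 libraries (adjusted p = 0.0563). In the knockout 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.177), with Per2 at 1.29 (SE 0.26), Cry2 at 1.48 (SE 0.27) and Clock at -0.91 (SE 0.22). The labels do not give the time of day at which muscle was taken. For age in wild type muscle the list was no longer called without 1 of 7 libraries: young wild type replicate 1 (adjusted p = 0.0644) or 4 (0.144), old wild type replicate 2 (0.0863) or 4 (0.144), or young knockout replicate 1 (0.0523), 3 (0.0507) or 4 (0.0553).

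Genes of NAD metabolism were called singly, in both directions. Of 18 NAD synthesis genes 1 rose with age in the wild type, Naprt, the first enzyme of the pathway that Nadsyn1 completes (0.84, SE 0.25), and none did adjusted over the list alone. In the knockout 1 gene of this list rose, Nnt (1.64, SE 0.28, 1 adjusted over the list alone), which couples NADH to NADPH and does not itself make NAD. At 2 months Nadsyn1 was the gene of this list called between genotypes. Of 18 NAD consuming enzymes 2 rose and 1 fell in the wild type (3 and 1 adjusted over the list alone), among them Parp2 (0.53, SE 0.16) and Cd38, a NAD glycohydrolase (-0.83, SE 0.26). In the knockout 2 of these 18 rose and none fell (also adjusted over the list alone), with adjusted p = 0.292 by camera and 0.0445 by fry. Neither list was called by camera with age in the wild type (adjusted p = 0.401 for each). Fry's test for changes of members in either direction gave adjusted p = 0.00088 for synthesis and 2.27e-06 for consumption in the wild type, and 0.000672 and 0.000152 in the knockout. Many other lists passed it too, such as heat shock chaperones (6.76e-08 in the wild type and 1.08e-05 in the knockout). Others, such as B and plasma cell markers (0.708 and 0.713), did not. It therefore does not set the NAD lists apart. Of all tested genes 15% were called with age in the wild type and 14% in the knockout, in the fit of all 16 libraries. These shares do not compare the size of the age response between genotypes. In the wild type the calls of Naprt, Parp2 and Cd38 were lost in 11, 14 and 15 of the 30 alternatives.

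Muscle growth and regeneration genes were called singly. Of 23 growth factor signalling genes 4 fell and none rose in the wild type, also adjusted over the list alone, with Igf1 at -1.31 (SE 0.26) and the insulin receptor substrate Irs1 at -2.09 (SE 0.44). In the knockout 4 fell and 1 rose, with Igf1 at -2.02 (SE 0.27). Of 16 satellite cell and regeneration markers 5 rose and 1 fell in the wild type (7 and 2 adjusted over the list alone), with myogenin (Myog) at 2.44 (SE 0.53) and Chodl at -1.44 (SE 0.33). In the knockout 3 rose and 2 fell, with Myod1 at 2.05 (SE 0.48). Camera gave adjusted p = 0.291 and 0.293 for these lists in the wild type, and 0.379 and 0.868 in the knockout. Of 16 endothelial markers 3 fell in the wild type, also adjusted over the list alone, among them the angiopoietin receptor gene Tek (-1.06, SE 0.22), with camera adjusted p = 0.401. Of 21 immediate early genes 2 rose and 4 fell with age in the wild type (2 and 5 adjusted over the list alone, camera adjusted p = 0.16), with Nr4a3 at -3.53 (SE 0.52), Fosb at -3.49 (SE 0.79) and Jun at 1.83 (SE 0.39).

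Sec61g and Cox17 differed between libraries of a group. Sec61g, a small subunit of the protein channel of the endoplasmic reticulum, was at 14.9 to 18.6 CPM in young wild type replicates 1 to 3 and 50.7 CPM in replicate 4, and at 57.7 to 75.7 CPM in old wild type replicates 1 to 3 and 12.1 CPM in replicate 4. It was at 39.4 to 56.9 CPM in young knockout and 16.1 to 31.4 CPM in old knockout. Cox17 was at 41.1 CPM in young wild type replicate 4, against 19.8 to 24.5 CPM, and at 29.5 CPM in old wild type replicate 4, against 49.6 to 70.6 CPM.

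Nadsyn1 had 9 to 34 intron reads in each wild type library. In the knockout it had 11 in old knockout replicate 1 and 0 to 2 in the other 7 libraries.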
